A study of Mus musculus with 17 samples.

How the data were processed

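Libraries of splenic Foxp3-GFP+ Tregs were sequenced with a 67 bp read and a 9 bp molecular identifier, at a stated 27 M reads per library, per the labels' protocols. The authors deposited expected counts per gene for 17 libraries, and per the submitters' processing notes the reads were aligned with Bowtie2 to GRCm38, with Ensembl 102 transcripts. Whether molecular identifiers were used to remove duplicates is not given in the sources used here, so floors cover counting error only. The table holds 47643 rows, of which 47224 matched a symbol and GRCm38 coordinates in the annotation used here, and 5.87% of the values are not whole. Counts were rounded.

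The main test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, with TMM factors, filterByExpr on the groups and all 17 libraries in 1 fit. The threshold was 0.05 after Benjamini-Hochberg adjustment over 9986 rows, and the common biological coefficient of variation was 0.241. Standard errors were taken from the log2 fold change and its F statistic, and cover the spread between libraries. On simulated data for transgenic against control, with 9986 rows, 95% of rows changed by 2 on the log2 scale were recovered and 61% of those changed by 1, with 10 false calls. For knockout against control these were 84%, 52% and 7, and for transgenic against knockout 93%, 73% and 7. Nothing in the labels says how animals were assigned to libraries, so p-values measure the spread between these libraries. The titles' replicate numbers did not pair the libraries, and no 2 libraries of a group agreed within sampling noise. The 38 gene lists, 27 of pathways and 11 of other cell types, were tested with camera at a preset correlation of 0.01, with fry beside it, where 3 or more members were tested.

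Named rows were chosen by a rule fixed before the data were examined. It takes Nfkbid and Foxp3, the 10 highest and 10 lowest log2 fold changes among called rows with an average log2 CPM of at least 3 and groups that do not overlap, up to 4 called members of each list or the member with the smallest p, and the 10 rows called in opposite directions with the smallest product of adjusted p. Predicted, clone-named and receptor-segment rows were counted only. Some rows that the rule names are not reported here. Normalization (RLE, upper quartile), filters, DESeq2 1.42.0, limma 3.58.1 with voom, fits of 2 groups, a replicate block, unrounded counts and leaving out each library were tried beside these, as fixed before the data were examined. A change in r across rows of under 0.1 was counted as no change, a margin set by choice. Library totals were 3133388 to 4726615 counts.

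The register of rows was examined only after the counts of abundant genes had been seen, and went through several attempts. A line was scanned at 33 slopes. Windowed scans and 3 settings of a local path had been judged by eye first. Then 28 settings of the path, those 3 included, were scored by the log likelihood of held-out rows, after a first grid had its best value at its edge. Unmoved rows scored -1.533 per row, a straight line -1.488, and the chosen path, the best of the 28, -1.48. Of the 28 settings 13 scored below unmoved rows, 2 of the 3 first looked at among them. A row was said to lie on another gene only where the 15 settings above unmoved rows named the same gene with at least 67 bp of overlap and no close second. A row was taken as in register on the same terms. It was also so taken where most of its moved exon bases lay on its own exons and the 15 settings agreed, without the conditions on overlap and a second gene. The shift used the mean of all libraries and not the groups. Tables simulated in register returned a slope of 0, and tables simulated with a shift gave the right gene for 90 to 93.1% of rows with a mean count of at least 10, on a smoother shift than the real one may have. Moved rows often lay on genes with no known role in T cells, such as Actg2 for the Dguok row, so names of genes under moved rows were not used as identities in the comparisons. Counts summed by the gene under the moved rows are the exception. The closing sections give calls, list tests and a correlation on them, which hold only if the estimated shift is right. Whether the Tyrobp and Hcst rows count Nfkbid reads is also asked there and stays undecided.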

Results

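RNA was sequenced from Foxp3-GFP+ regulatory T cells (Tregs) of the spleen of NOD mice, a strain that develops autoimmune diabetes. Foxp3 is the transcription factor that marks Tregs, and Nfkbid encodes an atypical nuclear IkB protein that modulates NF-kB. The 17 libraries comprised 6 of Nfkbid transgenic mice, 5 of Nfkbid knockout mice and 6 of NOD controls. Each transgenic library came from 1 sample, and each knockout or control library from a pool of 2, so a comparison with the transgenic group also compares unpooled with pooled libraries. Totals ran from 3133388 to 4726615 counts per library, and 3 counts corresponded to 0.635 to 0.957 CPM, the library-scaled count.

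Many rows of the table did not behave as counts of the gene they name. B2m, Tmsb4x and Pkm, which nearly all cells transcribe, had 0 counts in every library, Actb had 0 to 7 and Eef1a1 had 0 to 2. Genes near the start of their chromosomes had high counts, with a mean of 8261.6 for Rps9, which starts at 3.7 Mb on chromosome 7, and 4834.5 for Rps20 at 3.8 Mb on chromosome 4. When each row's exons were moved along GRCm38 by a distance proportional to position, the agreement of counts with exon overlap, as the mean Spearman's rho over 20 chromosomes and across rows, was highest at 0.45 kb per Mb, with 0.545 against 0.51 unmoved and 0.439 at the mirrored slope. The common slope gave a higher rho than no move on 16 of the 20 chromosomes. On chromosome X it gave a lower one, 0.4 against 0.49. Rows whose moved exons stayed on the gene they name numbered 2877, rows on another gene 5301, rows without a clear gene 7083 and rows on no annotated exon 30356. Below, the first kind and the mitochondrial rows are called genes in register. All others are called rows, and their names are those of the table, not established identities. Nuclear genes in register were picked by the same estimated shift, so their names depend on it too. Whether that shift is right stays undecided. A long gene counts as in register also where its moved exons lie on other exons of the same gene, as for Ikzf2, Nt5e and Nrp1 with estimated shifts of 39.9, 38.4 and 62.8 kb, so such a row holds part of the gene's reads.

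**Figure D1:**
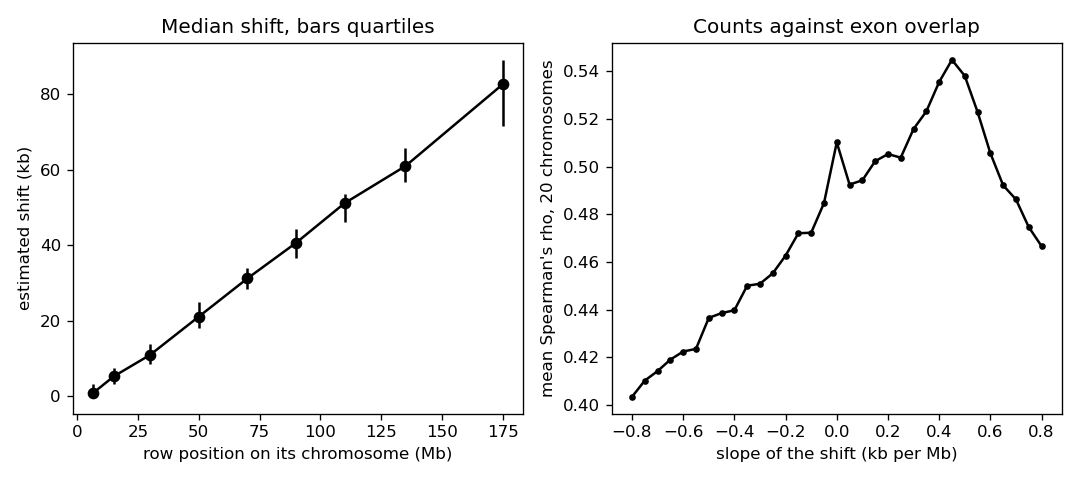
The left panel plots the median estimated shift in kb, with quartiles, against row position in Mb, and it rises from 0.9 kb at 3 to 10 Mb to 82.5 kb beyond 150 Mb. The right panel plots the mean Spearman's rho between counts and exon overlap over 20 chromosomes against the slope in kb per Mb, with a peak at 0.45 and a second, lower peak of 0.51 at no move.

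Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, GRCm38), in register, held 318.4 ± 22.05 CPM (SD, n = 6) in transgenic, 313.0 ± 40.9 (SD, n = 5) in knockout and 346.5 ± 15.51 (SD, n = 6) in control libraries, with no call in any comparison. The Nfkbid row (ENSMUSG00000036931, chromosome 7, 30421732 to 30428746) held 8.79 ± 1.51 CPM (SD, n = 6) in transgenic, 4.75 ± 2.41 (SD, n = 5) in knockout and 4.57 ± 0.915 (SD, n = 6) in control libraries. Its log2 fold change was 0.94 (SE 0.28, adjusted p = 0.045) for transgenic against control, 0.06 (SE 0.3, adjusted p = 0.914) for knockout against control and 0.87 (SE 0.3, adjusted p = 0.065) for transgenic against knockout. The first call ended when any 1 transgenic or control library was left out, with values of 0.85 to 0.99. The exons of this row, moved by 10.4 to 21.2 kb depending on the setting, lay on Nfkbid in 0 of 15 settings of the shift. The row therefore does not check the genotype labels, and groups below are those of the labels. The neighbouring rows Tyrobp and Hcst rose in transgenic libraries by 6.04 (SE 0.19, adjusted p = 2.7e-15) and 8.1 (SE 0.39, adjusted p = 5.3e-12) on the log2 scale, and neither has a clear gene.

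The comparison of transgenic with control libraries asks which transcripts differ when Nfkbid is added. Among genes in register, Izumo1r, the Treg folate receptor, rose by 0.58 (SE 0.09, adjusted p = 7.8e-05), Nt5e, the ectonucleotidase CD73, rose by 0.5, and Ikzf2, the Treg transcription factor Helios, rose by 0.48 on the log2 scale. Cd83, an activation marker, rose by 1.25 (SE 0.16, adjusted p = 1.3e-05). Tnfaip3, the NF-kB inhibitor A20, fell by 1.49 (SE 0.33, adjusted p = 0.005). It ran from 122 to 296 CPM in transgenic, 117 to 519 in knockout and 312 to 868 in control libraries. Some knockout libraries were thus as low as transgenic ones, without a call in knockout against control. Satb1, a chromatin organiser, fell by 0.5, Nrp1 fell by 1.2 and St8sia6 fell by 1.31. The Nrp1 call ended in 8 of the 29 alternatives run. In all, 522 rows were higher and 217 lower of the 9986 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 122 and 55 were in register. Without knockout replicates 2, 3 and 5, in which fewer rows were detected and which enter through the shared dispersion and the filter, 879 were higher and 469 lower, an alternative chosen after seeing the data. Without control replicate 3 or transgenic replicate 5 alone, 140 and 143 were lower.

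Among the lists fixed before the data were examined, the Treg identity list had 13 tested members, of which 4 rose and 1 fell, with 6 higher when adjusted over the list alone, and it was not called (camera adjusted p = 0.110). The members that rose were Izumo1r, Nt5e, Ikzf2 and the Entpd1 row (1.1), and Nrp1 fell. Of the 19 tested NF-kB target rows, 4 rose, which were Cd83, the inhibitors of apoptosis Birc2 (0.42) and Cflar (0.35) and the Relb row (0.44), and Tnfaip3 fell, with 6 higher and 3 lower when adjusted over the list alone. The calls of Birc2, Cflar and the Relb row ended in 11 of 29, 8 of 29 and 13 of 28 alternatives. The list was not called (camera adjusted p = 0.616). Fry, which asks whether members move on balance in 1 direction and does not compare them with other rows, gave an unadjusted p = 9.8e-04 for the Treg identity list and an unadjusted p = 0.001 for the NF-kB target list. Of 16 rows of the NF-kB and IkB family, 3 rose, among them the Bcl3 row at 1.25 (SE 0.2), which has no clear gene. The interferon gamma list had 6 of 14 rows higher, 9 when adjusted over the list alone (camera adjusted p = 2.2e-06, and adjusted p = 0.065 with an estimated correlation) and the type I interferon list 6 of 15, by either adjustment (camera adjusted p = 7.7e-05, and adjusted p = 0.065 with an estimated correlation), with 0 and 2 tested members in register. The Ifit3, Rsad2 and Gbp5 rows, named after interferon-induced genes, rose by 1.74, 2.29 and 1.19. The resting Treg list was lower (camera adjusted p = 0.015, and adjusted p = 0.074 with an estimated correlation), with Satb1 its only called member of 11. The list of NK cell markers was called (camera adjusted p = 5.1e-12, and adjusted p = 1.0e-04 with an estimated correlation) with the Tyrobp row its only called member of 3, a median of -0.2 and a mean of 1.84. The list of genes next to Nfkbid was called (camera adjusted p = 7.7e-05, and adjusted p = 0.004 with an estimated correlation) with the Tyrobp, Hcst and Thap8 rows its called members of 21 and a median of 0.08. No other list of another cell type was called. None of these 5 called lists had 3 members in register, so none could be tested on genes in register alone.

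The naming rule ranks called rows with an average log2 CPM of at least 3 and groups that do not overlap, without the rows that were counted only. Within these limits the highest log2 fold changes were in the Tyrobp, Abhd4 (5.68), Arhgap30 (5.54), Spire2 (5.04), Dguok (3.27), Pgghg (3.09), Oas1b (2.89), Sh3gl3 (2.88), Cers5 (2.74) and Penk (2.73) rows, and none of these was in register. The Abhd4, Arhgap30 and Spire2 rows were as high in knockout against control, at 5.46, 5.22 and 5.14, with transgenic against knockout at 0.22, 0.32 and -0.1 and not called, so they set the controls apart from both other groups. Identifiers in the library names also set the controls apart from both other groups, and their meaning was not established. The Oas1b and Penk rows also rose in knockout libraries, by 2.11 and 1.39, and the Dguok row fell by 4.11, to at most 1.3 CPM. Of the lowest, the AI504432, St6galnac2, Cd244a, Olfr411, Sesn1 and Slc25a44 rows had log2 fold changes of -1.48, -1.37, -1.35, -1.29, -1.23 and -1.19. Of these, the AI504432, St6galnac2 and Slc25a44 rows were also called lower in knockout against control, at -1.75, -0.48 and -0.93.

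The comparison of knockout with control libraries asks which transcripts differ when Nfkbid is lost. Among genes in register, AI838599 (chromosome 4, 3242055 to 3258092) fell by 5.21 (SE 0.42, adjusted p = 2.1e-07), Hdac9, a histone deacetylase, fell by 3.96 (SE 0.59), Dagla fell by 1.66, Arhgap19 fell by 1.38, Mbnl3 fell by 1.14 and Dab2ip fell by 0.89. In knockout libraries AI838599 held at most 1.43 CPM and Hdac9 at most 0.559, where 3 counts were 0.81 to 0.866 CPM. Counts this low leave the size of both changes poorly measured. Izumo1r fell by 0.35 (SE 0.09, adjusted p = 0.048) and Ikzf2 rose by 0.53 (SE 0.13, adjusted p = 0.041), calls that ended in 21 and 18 of the 28 alternatives run, with values of -0.39 to -0.3 and of 0.24 to 0.59. The Prdm1 and Entpd1 rows, which have no clear gene, fell by 1.82 (SE 0.3, adjusted p = 0.001) and 1.55 (SE 0.31, adjusted p = 0.010). In all, 88 rows were higher and 101 lower, 13 and 38 of them in register. Of these calls, 22 lay in the first 10 Mb of chromosome 14, and all 22 were lower here and higher in transgenic against control. Over genes in register, 30 were called in these opposite directions, and 8 without that segment. Knockout replicates 2, 3 and 5 had 13615, 13476 and 13802 rows above 0, against 15039 and 15931 in replicates 1 and 4, and left without these 3, an alternative chosen after seeing the data, the counts were 10 and 33. They also moved by more than 1.5 times when single libraries were left out. They were 592 and 532 without knockout replicate 4, 448 and 358 without knockout replicate 1 and 289 and 229 without transgenic replicate 1, while 29 to 50 were higher without knockout replicate 2, 3 or 5 or control replicate 1, 3, 4, 5 or 6, and 55 to 61 lower without knockout replicate 3 or 5 or control replicate 1, 3 or 5.

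**Figure D2:**
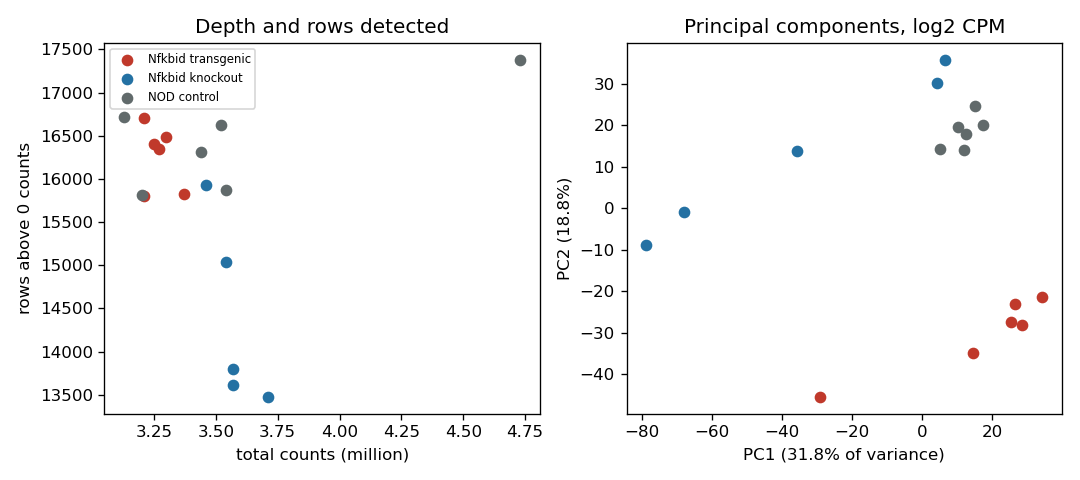
The left panel plots rows above 0 counts against total counts in M for the 17 libraries, coloured by group, and the 3 knockout libraries with the fewest rows lie between 13476 and 13802. The right panel plots the first principal components of log2 CPM, which hold 31.8% and 18.8% of the variance. On the first, knockout replicates 2, 3 and 5 lay at -78.8, -35.7 and -68 and transgenic replicate 1 at -29.1. All other libraries lay at 4.2 to 34.2, so the first component did not follow the groups.

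The mitochondrially encoded list, in register, was higher in knockout libraries (median log2 fold change 0.4, camera adjusted p = 1.7e-05, and adjusted p = 0.714 with an estimated correlation), with 0 of 13 members called over all rows and 11 higher when adjusted over the list alone. The mitochondrial share of counts was 25.56, 25.31 and 28.16% in knockout replicates 2, 3 and 5, and 22.04 and 22.55% in replicates 1 and 4, against 20 to 24.05% in controls and 19.66 to 24.81% in transgenic libraries. Replicates 1 and 4 lay within the range of the controls, and the 3 replicates with fewer rows detected lay above it. Without those 3 the list was not called (camera adjusted p = 0.56). The type I interferon list had 4 of 15 rows higher, 7 when adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.280 with an estimated correlation), among them the Ifit3 row at 1.11 and the Slfn5 row at 0.78. Without the same 3 libraries it was called (camera adjusted p = 0.00011, and adjusted p = 0.34 with an estimated correlation). The calls of the Ifit1bl1 and Trim30a rows ended in 17 and 11 of the 27 alternatives run, and those of the Ifit3 and Slfn5 rows in 3 and 1. At the preset correlation the type I interferon list was thus higher than in controls in both genotypes. With an estimated correlation it was called in neither (camera adjusted p = 0.065 for transgenic and camera adjusted p = 0.280 for knockout). Between transgenic and knockout libraries it was not called (camera adjusted p = 0.763), with 0 of 15 rows called. The effector Treg list was lower (camera adjusted p = 0.006, and adjusted p = 0.131 with an estimated correlation), with the Prdm1 row its only called member of 7 and 3 lower when adjusted over the list alone. Without those 3 libraries it was not called (camera adjusted p = 0.14).

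Transgenic against knockout libraries compared the highest with the lowest expected Nfkbid dose. Izumo1r was higher by 0.93 (SE 0.09, adjusted p = 3.0e-07), Ctla4, an inhibitory receptor of Tregs, by 0.75 (SE 0.21, adjusted p = 0.021), Nt5e by 0.52, Cd83 by 0.94 and Tnfsf8 by 1.02 on the log2 scale, all in register. The replication genes Mcm3 and Mcm4 were higher by 0.97 and 0.76, also in register, while 3 of the 15 tested proliferation rows were called and the list was not (camera adjusted p = 0.788). Nrp1 and Osm had log2 fold changes of -1.21 and -0.83, and the Nrp1 call ended in 8 of the 28 alternatives run. In all, 633 rows were higher and 432 lower, 160 and 93 of them in register. Lower rows were 826 without transgenic replicate 1, 649 without knockout replicate 4, and 262, 271, 277 and 269 without transgenic replicates 6, 4 and 5 and knockout replicate 5 in that order, and 208 without knockout replicates 2, 3 and 5. The effector Treg and suppressive molecule lists were called (both camera adjusted p = 0.029), and neither with an estimated correlation (adjusted p = 0.132 and adjusted p = 0.201). The mitochondrially encoded list was lower (median -0.32, camera adjusted p = 0.007, and adjusted p = 0.691 with an estimated correlation), and without knockout replicates 2, 3 and 5 it was not called and its direction turned (camera adjusted p = 0.91). The lists of NK cell markers and of genes next to Nfkbid were called as against control (camera adjusted p = 3.5e-07 and camera adjusted p = 0.007, and adjusted p = 0.002 and adjusted p = 0.035 with an estimated correlation), the second with a median of -0.08 and a mean of 0.8. Without those 3 libraries neither was called with an estimated correlation (adjusted p = 0.066 and adjusted p = 0.082). The Ighg2b row, named after an immunoglobulin gene, was higher by 4.43.

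Across the 9986 rows, which are not independent replicates, the log2 fold changes of transgenic and knockout libraries against the shared controls had Pearson r = 0.056 and Spearman rho = 0.306, with a covariance of 0.018. Simulated unchanged groups against the same controls gave a mean r of 0.471 and a covariance of 0.0416, and with the controls split between the comparisons r was 0.101 and the covariance 0.027. The relation rested in part on 1 segment: without the first 10 Mb of chromosome 14, a subset chosen after seeing the data, r was 0.293, rho 0.325 and the covariance 0.075, with the simulated one taken over all rows. Rows called in both comparisons were 38 higher in both, 16 lower in both, 46 higher in transgenic and lower in knockout and 0 the other way, where independent lists would give 4.6, 2.2, 5.3 and 1.9. The shared controls favour calls in the same direction, so for 38 and 16 these are not the counts of unchanged groups. Of the 46, 24 lay outside the first 10 Mb of chromosome 14. The in-register genes Izumo1r, Dab2ip, AI838599 and Hdac9 were among those called in opposite directions. Pearson's r was negative in several alternatives, among them -0.022 without transgenic replicate 1 and -0.487 over genes in register, where it rested on the first 10 Mb of chromosome 14. Spearman's rho over genes in register stayed positive, at 0.212.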

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

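The tests of the register of rows on held-out rows and of total depth were chosen after the result was seen, and the others before. Of 168 groups of values examined, 16 held a library set apart from the rest of its group, and chance gives about 1 in 20. NOD control replicate 1 had 4.73 M counts. Transgenic replicate 1 had a TMM factor of 0.864, and stood apart in the AI504432 row at 10.7 CPM, the Abhd4 row at 37.7, the Endod1 row at 166.0, the Ly9 row at 22.5, the Siglecg row at 33.2 and the Tbxas1 row at 169.0 CPM. Knockout replicate 5 stood apart in the in-register gene Arhgap19 at 1.96 CPM and the Dguok row at 0.0 CPM, and knockout replicate 2 in the in-register gene Dab2ip at 14.3 and the Dclre1b row at 43.0 CPM. Transgenic replicate 4 did in the Fech row at 9.97, control replicate 2 in the Egfl8 row at 17.7, control replicate 3 in the Ly9 row at 48.4 and control replicate 6 in the Them5 row at 5.82 CPM.

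Abundant genes at 0 counts were the widest pattern. A candidate explanation is that rows are out of register with the genes they name, for instance because gene coordinates of the reference were laid on a strain sequence with insertions and deletions, which was not tested directly. Held-out rows scored -1.48 with a local shift, against -1.533 unmoved, -1.561 at the mirrored slope and at best -1.591 with permuted counts. Permuting breaks the relation of counts to exons, and unmoved rows also scored above it, so that comparison cannot tell whether rows are shifted. The common slope was chosen on all rows, held-out ones included. The gain of the local path over a straight line, at -1.488, was small. On chromosome X and 3 other chromosomes the common slope did no better than no move. That the moved rows lie on the genes that were sequenced stays undecided, since the ribosomal protein list reached a median percentile of 75.1 on 6 members, below the 90 set beforehand and above the 57.7 of the list as deposited, which was taken over a wider set of genes. The same members stood at 52.0 as deposited. No biological explanation was tested.

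Knockout replicates 2, 3 and 5 detected fewer rows. Their lowest total was 3.57 M counts, no less than those of replicates 1 and 4, which argues against a lower number of counts. Whether duplicates were removed is not known, so totals cannot tell whether these libraries held fewer distinct molecules. After every library was thinned to 2502361 nuclear counts, a gap of 1129 rows to replicates 1 and 4 stayed, which argues against the mitochondrial share alone. RNA quality and a biological difference within the group were not tested and stay open.

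The transgenic libraries and 2 of the controls carry adjoining library identifiers, and the labels give no meaning for these. No knockout library shares a run of identifiers with a control, so such a series and the knockout cannot be told apart. The library names also hold identifiers that begin with JF in all controls and with NA in all other libraries. Their meaning was not established, so whatever they mark cannot be told apart from a difference of the controls from both genotypes. Against those 2 controls the median signed log2 fold change of called rows was 0.84 times that against the other 4, so a shared series does not account for the calls. Rows within 10 Mb of Nfkbid made up 1.9% of all rows tested and 0.5% of the knockout calls. That argues against a segment linked to that locus as the cause of most knockout calls. Such rows made up 2.6% of the transgenic calls. The labels do not say where the transgene lies, so the bound set beforehand was wrong for it. A segment linked to the transgene stays open. Among 277 windows of 10 Mb, the first of chromosome 14 held the most calls, a count made after the result was seen, with 52 of its 60 rows called in transgenic against control, 22 in knockout against control and 22 of the 46 rows called in opposite directions. For transgenic against control, 1 of 100 splits called as many rows, the real one with 739, and the highest other called 4. For knockout against control it was 1 of 100, with 189 against 19. For transgenic against knockout it was 2 of 100, with 1065 against 1820 in a split that put knockout replicates 1 and 4 with 4 transgenic libraries, which points to a structure of the libraries besides the groups. Few splits thus called as many rows as the real groups. The splits cannot tell genotype from anything else that follows the groups, and they do not exclude that structure. Pooling was confounded with the transgenic group.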

How the results depend on the processing

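Alternatives with rows in register, moved rows, 3 knockout libraries left out or 2 controls were chosen after seeing the data, and the cause of a move was not tested except where fewer rows or libraries were used. Named rows did not change direction where they were called, under any alternative run. Of their checks under alternatives fixed beforehand 4878 left a row called or uncalled as before, 398 ended a call and 82 made one. Under those chosen later these were 251, 77 and 6. The unchanged checks include rows called in neither fit, so they are not a share of calls that stayed. The calls ended most often were those of Izumo1r and Ikzf2 in knockout against control (21 and 18 of 28) and of Pfkp and Crem in transgenic against knockout (20 and 19 of 28). In transgenic against control Tyms lost its call in 15 of 29, the Relb row in 13 of 28, Birc2 in 11 of 29, and Cflar and Nrp1 in 8 of 29 each. Nrp1 lost its call in transgenic against knockout in 8 of 28. At this depth 3 counts are 0.635 to 0.957 CPM.

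Higher and lower rows in knockout against control were 223 and 348 without a low-count filter, 305 and 268 with DESeq2, 30 and 28 with limma voom, 34 and 42 with only the 2 groups, 30 and 47 in register and 10 and 33 with 3 knockout libraries left out. In transgenic against control they were 1010 and 664 with limma voom, 785 and 441 with the 2 groups, 133 and 61 in register, 879 and 469 with 3 knockout libraries left out and 207 and 45 against 2 controls, and 335 higher with moved rows. In transgenic against knockout, lower rows were 203 with the 2 groups, 208 with 3 knockout libraries left out, and higher and lower 171 and 114 in register and 385 and 273 with moved rows. Replicate numbers did not pair the libraries, and with the replicate block 23 and 44 rows were called in knockout against control and 214 lower in transgenic against knockout.

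The Nfkbid row in transgenic against control was no longer called at 0.89 with upper-quartile factors, 0.95 with either other filter and 1.21 against 2 controls, and in transgenic against knockout was called at 0.87 with DESeq2 and at 1.18 without knockout replicate 1, so both the tool and 1 library decide that call. Lists called were 2, 0 and 2 in the 3 comparisons with the estimated correlation, and 0, 1 and 1 in register, where 12 lists could be tested and 0 of the 5, 1 of the 3 and 2 of the 5 called lists were among them, and 9 with moved rows in transgenic against control. They were 3 and 1 with limma voom in transgenic against control and transgenic against knockout, 3 without a filter in the latter, and 1 in knockout against control with 3 knockout libraries left out. The relation r was 0.35 without a filter, 0.169 with the 2 groups, 0.191 at an average log2 CPM of at least 3 and without Nfkbid, and turned to -0.487 in register, -0.21 with moved rows and -0.099 with 3 knockout libraries left out. The value in register rested on the first 10 Mb of chromosome 14, without which it was 0.102, and over all rows r was 0.293 without that segment. Spearman's rho in register, with that segment, was 0.212 and did not turn.

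Leaving out each library gave 29 to 592 higher and 55 to 532 lower rows in knockout against control, 389 to 596 and 140 to 280 in transgenic against control and 473 to 815 and 262 to 826 in transgenic against knockout, -0.24 to 0.24, 0.85 to 0.99 and 0.69 to 1.18 for the Nfkbid row in that order, 2 to 4, 4 to 5 and 3 to 6 lists, and -0.022 (without transgenic replicate 1) to 0.122 for r.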

Other observations

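All tests in this part were chosen after the other results had been seen. Counts were summed over the moved rows that lay clearly on 1 gene, and 4226 such genes were tested. These names are those of the genes under the moved rows and hold only if the estimated shift is right, which stays undecided. Of the lists fixed beforehand, 9 were called for transgenic against control, 3 for knockout against control and 5 for transgenic against knockout. The proliferation list was higher in transgenic than in knockout libraries (camera adjusted p = 3.3e-10, and adjusted p = 0.047 with an estimated correlation) and than in controls (camera adjusted p = 9.2e-07, and adjusted p = 0.052 with an estimated correlation), and lower in knockout than in control libraries (camera adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). The other lists called for knockout against control, type I interferon and mitochondrially encoded, were not called with an estimated correlation (adjusted p = 0.36 and adjusted p = 0.58), so none of the 3 stayed. For transgenic against knockout the effector Treg list stayed besides proliferation (adjusted p = 0.014), and the interferon gamma, TNF receptor superfamily and mitochondrially encoded lists did not (adjusted p = 0.3, adjusted p = 0.057 and adjusted p = 0.6). Against control, the list of NF-kB targets was higher in transgenic libraries (camera adjusted p = 0.0074, and adjusted p = 0.039 with an estimated correlation), as were the type I interferon, effector Treg and TNF receptor superfamily lists (each adjusted p = 0.022 with an estimated correlation), the last 2 on 3 genes each, and the resting Treg list was lower (adjusted p = 0.043 with an estimated correlation). The co-inhibitory, interferon gamma and heat stress lists were not called with an estimated correlation (adjusted p = 0.083, adjusted p = 0.065 and adjusted p = 0.29).

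A candidate explanation of the higher Tyrobp and Hcst rows in transgenic libraries is that these rows count Nfkbid reads. The moved exons of the Tyrobp row lay on Nfkbid in 11 of the 15 settings of the shift and those of the Hcst row in 3, at shifts of 10.4 to 21.2 kb. The settings disagree, so the source of these reads stays undecided. In knockout libraries the rows had log2 fold changes of 0.38 (adjusted p = 0.268) and 1.56 (adjusted p = 0.170) against control, neither called.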
